A study of Mus musculus with 8 samples.

How the data were processed

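Mouse neuronal stem cells, described in the labels as p16Ink4a and p14Arf negative, were stably transduced with wild-type H3.3 or H3.3K27M and fixed with 1% formaldehyde for 15 min. Per the labels, 30 ug of chromatin and 4 ul of antibody went into each immunoprecipitation. Groups were taken from the sample titles, giving 8 samples with 1 library for each of 2 genotypes and H3K4me3, H3K27ac, H3K27me3 and input. Intervals of the 6 immunoprecipitated libraries were used, and the inputs were not used here. Cells were grown in Neurobasal A medium with EGF and bFGF, per the labels' protocols.

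The authors deposited interval tables with 1 list per library, and the libraries were not pooled. Per the submitters' processing notes BWA and SICER were used with mm10; their versions and roles, the caller used for each mark, the call thresholds and any use of the input libraries are not given in the sources used here. Counting both end positions, the lengths of all H3K27me3 intervals were multiples of 200 bp, and the lengths printed here are end minus start. Per the file headers each interval has a mean and a highest value, which are a signal or coverage: the deposited values are tag densities in bins of about 32 nt. Mean density times the number of bins was a whole number (tolerance 0.05) in 98.7% to 100% of intervals per library, so the densities were not multiplied by a library factor after counting. Whether tags were first sampled to a common number, and whether any spike-in was used, is not given in the sources used here. The densities are the authors' own, and the total depth of the libraries is unknown, so a difference in scale between the 2 libraries of a mark cannot be separated from a genome-wide change.

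Because the lists were called separately, the number of intervals, the covered length and the overlap by at least 1 bp were compared first. Overlapping intervals of the 2 genotypes of a mark were then merged into regions, called shared when both lists had an interval there. In shared regions the ratio was log2((K27M density + 1) / (wild-type density + 1)), which understates changes at low density, with the mean density of each library over its own intervals. A ratio of densities in regions called in both is a description of these libraries at the deposited scale. It does not include regions lost from one list. The lengths called in the 2 libraries can differ widely within a shared region, and the ratio takes no account of this. Where the median ratio over all regions lay more than 0.1 from 0, some ratios are given relative to that median and are named as relative. All others are at the deposited scale. The sums of density over all called intervals, used for one alternative scaling, stood at 7.46, 2.17 and 0.752 for wild type over K27M in H3K27me3, H3K27ac and H3K4me3. These sums move with the covered length, whose ratios were 5.49, 2.51 and 0.971, and the mean densities over covered bases were 6.84 and 5.31, 38.9 and 45.0, and 68.9 and 88.9.

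Promoter and CpG island notes came from the deposited tables. Genes came from a RefSeq table of GRCm38.p6, the assembly of mm10, limited to 24350 genes with curated transcripts. The table gives no strand, so a gene took the regions that overlapped its span with a flank of 1 kb, and not the region nearest to its start site as first planned. With several regions the one with the highest mean density of both libraries was used. A gene counted as marked in a library when any merged region overlapping it held an interval of that library, even outside the gene and its flank. Of 548 list symbols 547 were matched, 2 of them through a synonym, and Hist1h genes were also found through synonyms.

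The gene lists, the rule for named genes, the thresholds and most of the alternative settings were fixed before the data were examined. Named were, for each mark, up to 10 genes with the highest and 10 with the lowest ratio among genes at least 2-fold changed whose higher density reached the median over regions, 1 per region and leaving out predicted and olfactory genes, then the extreme 2 members at each end of every list, and a fixed set (Hist1h genes, H3f3a, H3f3b, Ezh2, Hk2, Glud1, Idh1, Cdkn2a, Cdkn1a). A few genes that the rule takes are not reported here. Other members named beside them, the Hox clusters as loci and regions found in 1 library alone were picked after their values were seen. The lists covered glycolysis, the TCA cycle, glutamine and glutamate metabolism, serine and one-carbon metabolism, oxidative phosphorylation, H3K27 and H3K4 modifiers, PRC1 components, Hox clusters, non-neural developmental regulators, neural patterning and neuronal fate regulators, neural stem and progenitor, mature neuron, astrocyte, oligodendrocyte, microglial, endothelial and mural, fibroblast and mesenchymal, cell cycle, cell cycle inhibitors and p53 pathway, housekeeping, imprinted, protocadherin, and Wnt, BMP and Hedgehog genes.

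For each list with at least 3 shared members the median ratio was placed among 10000 random lists of the same size matched on mean density in deciles, and a list stood apart at or under percentile 2.5 or at or over 97.5. The same was done for the share of members marked in the wild-type library that were also marked in the K27M library, a measure added after the tables were seen. Percentiles describe these libraries and are not p-values. Shares have Wilson intervals and medians have intervals from binomial order statistics, both at 95%. Alternatives covered the pseudocount, the scaling, the density floor, the fold threshold, highest in place of mean density, the overlap, the sex chromosomes and the choice of region per gene.

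The steps were tested on simulated data. With wild-type intervals kept or dropped at random, 0 of 10261 kept H3K27me3, 19573 kept H3K27ac and 11679 kept H3K4me3 intervals were missed. Of 200 intervals changed 4-fold in each of these marks, 118, 146 and 133 lay in regions of 1 interval per library, and the change was recovered in all of these. Kept intervals were copies shifted by less than their own length, so their overlap was certain and only the code was checked. The copies had no noise and no pseudocount was used. Scatter, differing lengths and the assignment of regions to genes were not tested. Of 200 random lists 7.00% fell outside the central range, and 98.0% of 100 lists of 20 members shifted by 0.3 log2 among 5000 genes were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.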

Results

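Chromatin immunoprecipitation sequencing was carried out on 8 samples of mouse neuronal stem cells that stably carried either wild-type histone H3.3 or H3.3K27M, in which lysine 27 of the histone variant is replaced by methionine. The same change in human H3.3 is found in diffuse midline gliomas. H3K27me3, the mark laid down by Polycomb repressive complex 2, H3K27ac, a mark of active promoters and enhancers, and H3K4me3, a mark of promoters, were profiled with 1 library per genotype and mark. The 6 libraries gave separate lists of enriched intervals in mm10 coordinates, each with a mean and a highest tag density. The total number of tags behind each list is unknown, so its depth could not be given, and the 2 input libraries were not used here. With 1 library in every group no difference had a replicate check and no p-values are given. All intervals in parentheses are 95% intervals that cover counting error only, and neighbouring regions are not independent.

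H3K27me3 covered far less of the genome in the K27M library than in the wild-type library. The wild-type list held 20705 intervals over 244 Mb and the K27M list 5877 intervals over 44.4 Mb, or 18.2% of the wild-type length. The intervals were also shorter, with a median of 4799 bp against 8399 bp, and their median tag density was 2.81 against 4.97. A K27M interval overlapped 3841 of the 20705 wild-type intervals (18.6%, 18.03 to 19.09), whereas 86.6% of the K27M intervals lay on a wild-type interval. With 1 density floor for both lists the wild-type list held 12.6 times as many intervals instead of 3.52 times and 10.2 times the length instead of 5.49 times, and 7.02% of its intervals were overlapped. That floor was the wild-type 5th percentile (3.54), close to the upper quartile of the K27M list (3.63). A difference in scale alone would also widen these ratios, so the floor cannot tell scale from loss. At the level of genes, 7667 genes overlapped a merged region with a wild-type H3K27me3 interval and 3335 one with a K27M interval. That interval could lie elsewhere in the region, so these are upper counts of genes that carry the mark themselves. Counted this way, both lists marked 3243 of these genes. In the wild-type library alone 4424 genes (57.7%) were marked, and 92 in the K27M library alone.

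**Figure D1:**
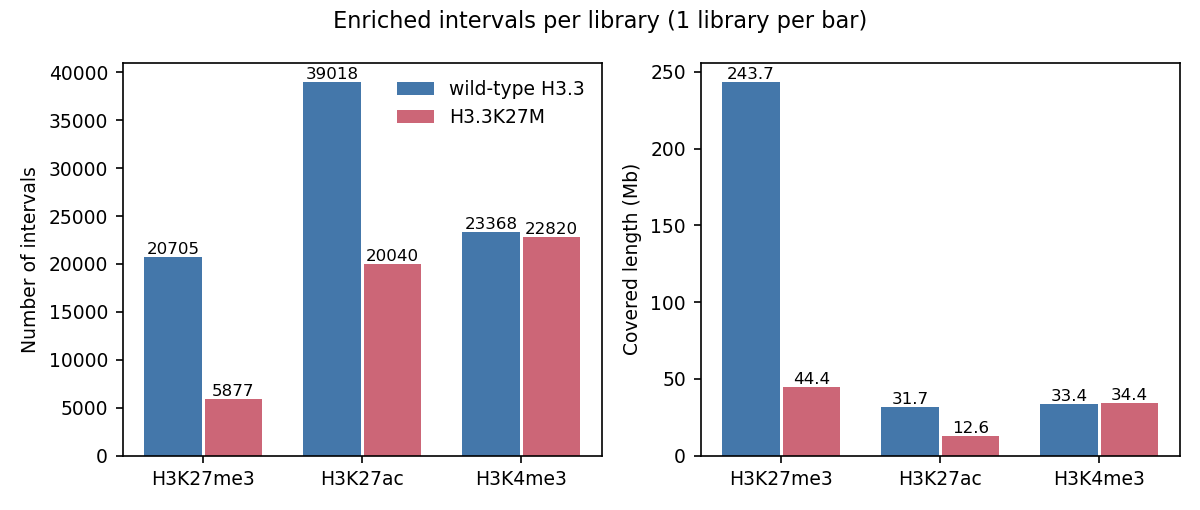
Number of enriched intervals and covered length (Mb) of the 6 libraries, with 1 library per bar and no error bars. The H3K27me3 bars go from 20705 intervals and 244 Mb with wild-type H3.3 to 5877 intervals and 44.4 Mb with H3.3K27M, and the H3K4me3 bars stand at 23368 and 22820 intervals.

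The wild-type intervals with the densest H3K27me3 were met most often in the K27M library. The overlapped share went from 5.65% in the lowest decile of wild-type density to 80.3% in the highest. Of the merged regions with a wild-type interval, 47.2% (45.4 to 49.1) of those with a CpG island were marked in both libraries, against 13.4% (12.9 to 13.9) of those without one, and 29.9% (28.8 to 30.9) of those at a promoter against 11.5% (10.98 to 12.06) of the others. These shares are not matched on density. Within a decile of wild-type density the gap by CpG island was smaller, with 86.7% of wild-type intervals overlapped against 75.1% in the highest decile, 49.3% against 37.5% in the next and 6.85% against 5.04% in the decile from 4.64 to 4.97. In the 3656 regions marked in both, the median log2 ratio of K27M to wild-type density was -1.11 (-1.13 to -1.09), with quartiles of -1.41 and -0.75. It was -1.23 at promoters and -0.92 elsewhere, not matched on density. In these shared regions the median wild-type densities were 8.74 and 6.52, and the median K27M densities 2.99 and 2.84. At the deposited scale 2120 shared regions were at least 2-fold lower in the K27M library and 5 at least 2-fold higher. Once the median shift of -1.11 was removed the split was 26 lower and 213 higher, and with the 5th percentiles of the lists made equal it was 390 and 82. A shared region needs a K27M interval, and the 5th percentile of K27M interval density was 2.02, which limits how low a ratio can be. The split after centring is therefore not a balance of losses and gains. With equal sums over the called intervals the median turned to 1.43 and the split to 0 and 3034. A scale factor of the whole library moves all of these ratios together and leaves the order of the regions nearly as it is.

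The 16864 regions with H3K27me3 in the wild-type library alone had no ratio and were left out of the ranking of genes. The densest of them lay at Kcnk12 (20.2). Among shared regions under the naming rule, Kcnn1, a calcium-activated potassium channel, had the deepest relative loss of H3K27me3 by mean density. It went from 20.2 to 2.63 in mean tag density, a log2 ratio of -1.44 relative to the median shift. Lingo3 followed at -1.41, the potassium leak channel Kcnk9 at -1.34, the noncoding Tbx3os1 and its neighbour Tbx3, which share a region, at -1.28, and the cation channel Trpm2 at -1.26. Shisa8 lay at -1.25, the homeobox gene Irx4 at -1.21, Chat, which makes acetylcholine, at -1.18, Tmem132e at -1.17 and Zfp879 at -1.17. On the deposited scale their log2 ratios ran from -2.55 to -2.27. The K27M densities of Chat (1.90), Kcnk9 (2.08) and Irx4 (2.10) lay near the 5th percentile of the K27M list (2.02), while Shisa8 stood at 4.45. Ratios of genes near that floor could hardly go lower, so their order depends on the wild-type density. By highest density the order differed, with Kcnk9 lowest of the 10 at -4.07 and Kcnn1 at -2.87. The length called in the K27M library was much shorter at some of them, with 799 bp against 17399 bp at Tmem132e, 5998 against 47999 at Tbx3os1, 3999 against 16799 at Chat and 5399 against 25999 at Irx4, so these ratios do not compare like regions. With equal sums 8 of the 10 turned to values above 0 and Kcnn1 and Kcnk9 came to -0.04 and -0.02.

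A small group of genes lay in regions with denser H3K27me3 in the K27M library on every scale tried. Abhd3 went from 3.79 to 12.2 (log2 1.47), the zinc-finger gene Zic4 from 5.44 to 15.6 (1.36), Rims1, a protein of presynaptic active zones, from 4.25 to 10.4 (1.12), the region of Hoxa11 and Hoxa13 from 5.76 to 12.8 (1.03), and Tenm2 from 4.48 to 10.01 (1.01). In the Hoxa11 and Hoxa13 region the dense K27M interval (17.9) began at 52261200, beyond both gene spans. The K27M interval that reached into Hoxa13 had a density of 4.51, against 6.49 for the wild-type interval there. No K27M interval reached Hoxa11. The called lengths also differed, from 7999 bp in the wild-type to 32599 bp in the K27M library at Abhd3 and from 26598 to 73799 bp at Zic4. All 5 fell under the 2-fold threshold with a pseudocount of 5, and Tenm2 also by highest density. Among developmental regulators below that threshold, the endodermal factors Foxa1 and Foxa2 had log2 ratios of 0.99 and 0.88, with 6599 and 39799 bp called at Foxa1, the motor neuron factor Isl1 0.56 and the proneural factor Neurog2 0.24. By highest density Isl1 and Neurog2 turned to -0.16 and -0.41.

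Counted by merged region, Hox genes and non-neural developmental regulators kept H3K27me3 more often than random lists of the same wild-type density. All 23 Hox genes marked in the wild-type library lay in merged regions that also held a K27M interval. The share kept lay at percentile 99.995 of 10000 random lists. A further 7 Hox genes were marked in the K27M library alone. Hoxa11 counted by its region only, since no K27M interval reached the gene (52242105 to 52245810) or its flank. The nearest K27M intervals ended at 52240799 and began at 52247400. The 23 genes lay in only 6 regions, and with 1 member per region, as an alternative draw, the percentile for these 6 was 99.985. The median log2 ratio of the 23 genes was -1.18, equal to that of random lists (percentile 43.8), and 20 were at least 1.5-fold lower. Of 37 marked non-neural developmental regulators, 28 were marked in both (75.7% against 56.8% for random lists of the same wild-type density, percentile 99.98). The median log2 ratio of the 27 with a shared region was -0.96, against -1.30 for random lists (percentile 99.1), with Foxa1 highest and Tbx3 and Pitx1 (-2.07) lowest. With 1 member per region, as an alternative draw, that percentile was 94.8, and for lists matched on region length the share kept came to 96.6. Of 28 neural patterning and neuronal fate regulators 22 were marked in both, with a median of -1.01 (percentile 96.1; 97.52 when matched on length), from Isl1 down to Pax7 (-2.12) and Lhx5 (-1.81). Fibroblast and mesenchymal genes kept the mark less often than random lists, with 2 of 9 in both (percentile 2.05), a position that became 7.57 with promoter regions, 16.0 when matched on length and 3.09 with 1 member per region. Col1a1, Col6a1, Thy1, Fbln1, Snai2, Tgfbi and Cdh1 were the 7 marked in the wild-type library alone.

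The other lists did not stand apart for H3K27me3 at the main setting. The share kept by Wnt, BMP and Hedgehog genes lay at percentile 7.49, and at 2.48 with promoter regions. The median of mature neuron genes lay at percentile 47.6, and at 0.145 by highest density. Mature neuron genes had a median of -1.29 over 10 shared regions, with all 10 at least 1.5-fold lower, Chat and the GABA transporter Slc32a1 (-2.13) lowest and Nefl (-0.76) highest. Microglial genes were marked in the wild-type library in 11 cases and in both in 8, with a median of -1.27, and Ptprc alone had a ratio above 0 (0.50). Oligodendrocyte genes had a median of -1.32 over 4 regions, imprinted genes -1.33 over 10 genes in 6 regions with Ndn and Magel2 at -0.25, PRC1 components -1.02 over 5 with Pcgf2 highest at -0.56, and Wnt, BMP and Hedgehog genes -1.01 over 8 with Gli1 at -1.76 and Shh at -0.48. Both libraries marked 2 of 9 endothelial and mural genes, 2 of 5 astrocyte genes, 2 of 5 cell cycle genes (Bub1 at -0.07 and Cdk6 at -0.19), 2 of 4 H3K27 and H3K4 modifiers (Ezh1 and Crebbp), 2 of 2 neural stem and progenitor genes (Gfap at -1.37 and Msi1 at -1.48) and Cdkn1c (-1.47) alone among cell cycle inhibitors. For metabolism, both marked 2 of 6 glycolysis genes (Hk2 at -0.91 and Pfkm at -1.65), 2 of 5 TCA cycle genes (Suclg2 and Pcx) and 1 of 4 oxidative phosphorylation genes (Ndufb8). They marked 0 of 3 glutamine and glutamate genes, 0 of 3 protocadherins and 0 of 1 serine and one-carbon gene in common. None of 27 housekeeping genes carried an H3K27me3 interval in either list.

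The HoxD cluster went against the loss of H3K27me3, an observation picked after the values were seen. Between 74651989 and 74766142 on chromosome 2, H3K27me3 covered 7.80 kb (6.83%) in the wild-type library and 87.6 kb (76.7%) in the K27M library. H3K27ac covered 1.71 kb there in the wild-type library and 0 kb in the K27M library, and H3K4me3 4.53 and 3.01 kb. The densest H3K27me3 of all regions marked in the K27M library alone (17.2) lay in an interval that ended at 74655199. It covered only part of Evx2 (74652989 to 74661520), next to the cluster. Evx2 also overlapped a wild-type interval from 74657600 (4.23). The Hoxd3 and Hoxd4 interval had a density of 11.5. In the other clusters H3K27me3 coverage went from 65.0 to 56.2 kb at HoxA and from 162 to 130 kb at HoxB. HoxC was covered over its 118 kb in both libraries, by intervals that reached beyond the cluster. The mean density was 37.8 over the wild-type interval of 429799 bp and 21.4 over the K27M interval of 249799 bp. Other strong regions marked in the K27M library alone lay at Shox2 (11.2), Lin28b (10.1), Lhx9 (10.1), Tbx20 (8.68) and Foxp2 (6.91). Such a gene can also overlap another region with a wild-type interval, as Tbx20 did. In all, 789 H3K27me3 regions were found in the K27M library alone.

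**Figure D2:**
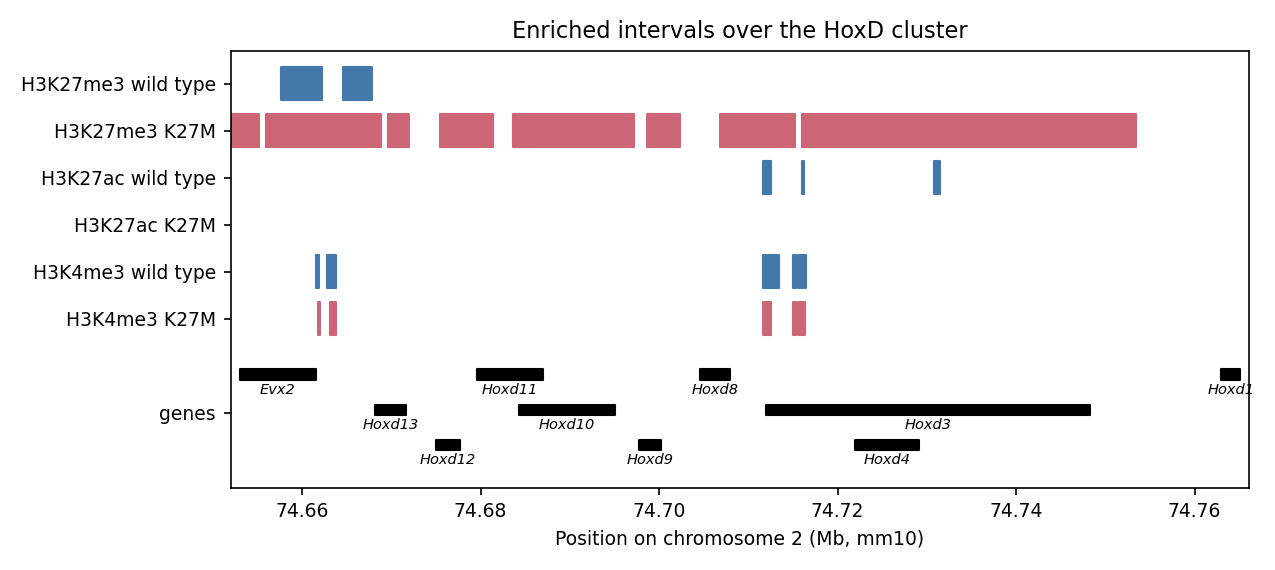
Enriched intervals of the 3 marks in both genotypes over the HoxD cluster, drawn to scale along chromosome 2 (Mb, mm10), with gene spans at the bottom and 1 library per track. H3K27me3 intervals span 7.80 kb of the window with wild-type H3.3 and 87.6 kb with H3.3K27M.

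H3K27ac was called in fewer places in the K27M library, while its density in the places called in both was nearly equal. The wild-type list held 39018 intervals over 31.7 Mb and the K27M list 20040 over 12.6 Mb. K27M intervals overlapped 39.7% (39.2 to 40.2) of the wild-type intervals, and wild-type intervals overlapped 94.9% of the K27M intervals. Genes with H3K27ac numbered 12551 and 10684, with 10523 in common. The regions missing from the K27M list were mostly distal: 59.0% (58.3 to 59.8) of regions with a wild-type interval at a promoter were found in both libraries against 20.8% (20.3 to 21.4) of the others, and 78.9% of those with a CpG island against 20.2% of those without. The density floor of the lists also differed, with 5th percentiles of 17.0 in the wild-type and 25.5 in the K27M list. At the higher floor in both lists the interval counts came within 1.06-fold of each other and 64.8% of the wild-type intervals were overlapped, while the wild-type list still covered 1.97 times the length, against 2.51 times without the floor.

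**Figure D3:**
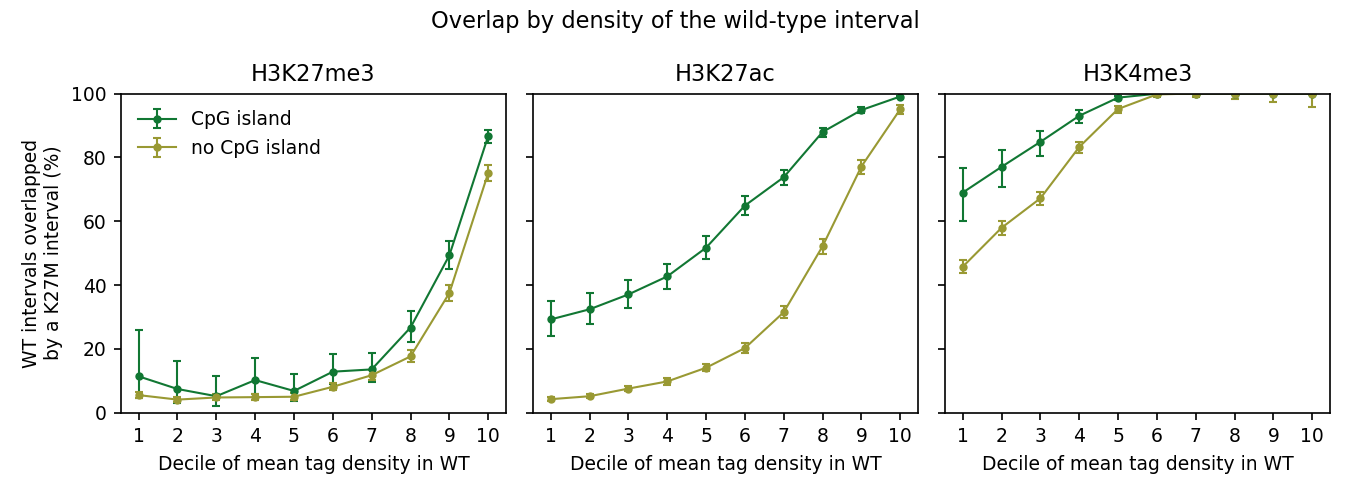
Share of wild-type intervals overlapped by a K27M interval (%) in each decile of wild-type mean tag density, for intervals with and without a CpG island, with 95% Wilson intervals as error bars. For H3K27ac the CpG island line lies above the other in the plotted deciles, and over all densities the share runs from 5.89% in the lowest to 98.1% in the highest decile.

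In the 14738 H3K27ac regions found in both libraries the median log2 ratio was 0.03 (0.02 to 0.03), and it was -0.28 by highest density, so that the direction depended on the measure. At least 2-fold changes of mean density were few, with 34 regions higher and 10 lower, or 29 and 17 after centring. By highest density they were more and the split turned, with 74 higher and 708 lower. Equal 5th percentiles turned the median to -0.54 and the split to 0 higher and 1165 lower, and equal sums gave 9557 higher and 0 lower. High ratios were found at Lpgat1 (19.7 to 48.0, log2 1.24), the RNA-binding protein gene Khdrbs3 (1.12), Pip4k2c (1.12), Mta3 (1.12), Xrcc5, the Ku80 subunit of DNA end joining (1.10), the mitochondrial aspartate-glutamate carrier Slc25a13 (1.06), Ttc26 (1.03), Sar1b (1.01) and Nfil3 (1.01). None of these genes reached 2-fold with equal 5th percentiles. The lowest were at Pald1 (60.1 to 26.4, -1.16), Tspan32 (-1.03) and Polr3b (-1.02), and the last pair turned to 0.06 and 0.07 with equal sums. The K27M list held only 246 bp at Pald1 and 322 bp at Tspan32, against 3466 and 3611 bp in the wild-type list, so their ratios do not compare like regions.

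Genes of the neural stem and progenitor list had lower H3K27ac density in the K27M library than other genes of the same density. The median over 25 genes was -0.31 against -0.03 for random lists, below the medians of all 10000 of them, and it stood apart under every alternative run. Of the 25, 21 lay below the median of all regions. The lowest were Zbtb20, a zinc-finger gene of hippocampal and glial development (56.1 to 29.9, log2 -0.88), and the RNA-binding protein gene Msi2 (-0.63). Nes, which encodes nestin, Olig2, Fabp7 and Sox2 had ratios of -0.52, -0.52, -0.47 and -0.36, and Ptprz1 (0.38) and Tnc (0.35) were highest. With equal sums the median over all regions was 1.12, so the place of these genes below other genes does not rest on the scale, while the sign of their ratios does. The 17 protocadherin genes also stood below all random lists (-0.46), though they took their values from 2 regions, too few for a median with 1 member per region.

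The medians of the other lists did not stand apart for H3K27ac at the main setting. Neural patterning genes had H3K27ac in 10 cases in the wild-type library, 9 of them in both (90.0% against 60.0% for random lists, percentile 98.3), with Dlx1 (0.66) and Emx2 (0.51) highest. That percentile was 89.8 with promoter regions, 84.7 when matched on length and 97.2 with no flank. The median of these 9 was 0.35 (percentile 96.0), and its percentile was 98.4 with promoter regions, 99.4 by highest density and 99.4 when matched on length. For metabolic genes the medians were -0.05 for glycolysis, with Pkm at -0.61 and the lactate transporter Slc16a1 at 0.40, 0.10 for the TCA cycle (percentile 94.8; 98.01 as the mean over all regions of a gene), with Mdh2 at -0.59 and Suclg2 at 0.50, 0.02 for glutamine and glutamate metabolism, with Slc1a3 at -0.53, 0.00 for serine and one-carbon metabolism and -0.03 for oxidative phosphorylation, with Cox4i1 at 0.73 and Uqcrc1 at -0.58. Chromatin genes lay at 0.05 for H3K27 and H3K4 modifiers, with Aebp2 at 0.55 and Rbbp7 at -0.57, and 0.05 for PRC1 components, with Bmi1 at 0.64. Cell cycle genes lay at -0.03, cell cycle inhibitors and p53 pathway genes at -0.20 (percentile 4.95; 2.03 with promoter regions and 1.41 when matched on length) with Bax at -0.56, housekeeping genes at -0.02 and imprinted genes at -0.10. Cell type lists gave 0.40 for 3 mature neuron genes, 0.03 for 7 astrocyte genes, 0.00 for 5 oligodendrocyte genes and -0.05 for 5 fibroblast genes. Wnt, BMP and Hedgehog genes gave 0.01, with Bmp7 at -0.72, and 3 non-neural regulators 0.26, with Tbx2 at 1.14. Too few members for a median were shared for Hox (2, both at 0.35; share kept at percentile 17.8 and at 1.78 when matched on length), microglial (1, Cd68 at -0.21) and endothelial and mural genes (2, Cspg4 at -0.25 and Pecam1 at -0.20).

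H3K4me3 was found at nearly the same genes and at most of the same promoters in both genotypes. The lists held 23368 wild-type and 22820 K27M intervals over 33.4 and 34.4 Mb, and 85.9% (85.4 to 86.3) of wild-type intervals were overlapped by a K27M interval. Of 13590 genes with wild-type H3K4me3, 13335 also had it in the K27M library, leaving 255 (1.88%), and 357 genes had it in the K27M library alone. Of 15486 promoter regions with a wild-type interval 14292 (92.3%) were found in both, and 2207 more promoter regions were found in the K27M library alone. Of the regions with a wild-type interval and a CpG island 98.4% were found in both, and 443 more regions with a CpG island were found in the K27M library alone. The median log2 ratio over 17790 shared regions was 0.35 (0.35 to 0.36), with 128 regions at least 2-fold higher and 5 lower. Once this shift was removed the split was 21 and 21, and with equal sums it was 14 higher and 25 lower around a median of -0.05.

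High H3K4me3 ratios relative to the median shift of 0.35 were found at a few genes. Dach1, a transcriptional cofactor of development, went from 16.9 to 78.4 in density (1.79 above the shift), followed by the sarcoglycan Sgcz (1.28), Egflam (1.19), Pcdh15 (1.11), Slitrk5 (1.11), Zdhhc23 (1.04), the mechanosensitive channel Piezo2 (1.03), the GABA receptor subunit Gabrb2 (1.02) and the heat shock protein gene Hspb8 (0.95). Rpl7a, a ribosomal protein gene, had the top value (17.9 to 120, relative 2.33), but the wild-type list held only a fragment of 291 bp there, against 6014 bp in the K27M list, so the ratio does not compare like regions. Dach1 also rested on a short wild-type interval of 376 bp against 1791 bp. Rap2a went from 83.1 to 40.0 (relative -1.39). It was the 1 gene at least 2-fold lower among those that reached the density limit of the naming rule. Strong H3K4me3 regions called in the K27M library alone lay at Tmem200c (106), Slc25a28 (101) and St3gal6 (83.5), and in the wild-type library alone at Recql4 and Lrrc14 (127).

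Neural patterning and neuronal fate regulators were the list with the highest percentile for the median H3K4me3 ratio. Of 23 genes with a shared region 10 were at least 1.5-fold higher and 0 lower, and their median was 0.55 against 0.35 for random lists (percentile 99.96). Measured from the median shift, 3 stayed at least 1.5-fold higher, and 18 lay above the shift. Lhx1, a LIM homeobox factor, went from 23.0 to 53.2 (relative 0.82) and Atoh1, a proneural factor, from 27.4 to 55.3 (0.63). Neurod2 (relative -0.42) and En2 (relative -0.33) were lowest. Oxidative phosphorylation genes lay slightly below random lists (0.30 against 0.38, percentile 1.42; 2.87 as the mean over all regions of a gene and 7.10 when matched on length). Protocadherins did too (0.29, percentile 1.85; 5.79 with promoter regions, 4.84 by highest density, 5.20 when matched on length and 10.9 with 1 member per region), from 6 regions. Hox genes had a median of 0.33 over 5 genes, with the region of Hoxa5 and Hoxa6 going from 60.9 to 19.5 (relative -1.95). The K27M list held only a fragment of 315 bp there, against 2073 bp in the wild-type list, so this ratio does not compare like regions. By the mean over all regions of a gene and by highest density the Hox list, with these genes among its members, lay at percentiles 0.05 and 0.57.

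The other H3K4me3 medians lay close to the shift of 0.35. Metabolic lists gave 0.36 for glycolysis, where Slc2a3 was highest (1.12), 0.33 for the TCA cycle, 0.39 for glutamine and glutamate metabolism and 0.36 for serine and one-carbon metabolism. H3K27 and H3K4 modifiers lay at 0.37 and PRC1 components at 0.42. Cell type lists lay at 0.35 for neural stem and progenitor, 0.30 for mature neuron with Snap25 lowest (-0.43), 0.48 for astrocyte, 0.33 for oligodendrocyte, 0.26 for microglial, 0.37 for endothelial and mural, and 0.45 for fibroblast and mesenchymal genes. Non-neural regulators lay at 0.41 (percentile 79.98; 98.2 with no flank), with Pax9 at 1.21, and Wnt, BMP and Hedgehog genes at 0.45 (percentile 95.01; 97.7 when matched on length), with Bmp4 at 0.74. Cell cycle genes lay at 0.33, cell cycle inhibitors at 0.33, housekeeping genes at 0.34 and imprinted genes at 0.38. Over the 3 marks, 6 of 52 list medians and 4 of 65 shares kept stood outside the central range of random lists.

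H3K4me3 and H3K27ac were also compared by whether H3K27me3 overlapped them. H3K4me3 regions with a CpG island were called in the K27M library alone in 2.02% (1.77 to 2.32) of cases without H3K27me3, 8.23% (6.74 to 10.02) where H3K27me3 was called in the wild-type library alone, and 10.9% (9.36 to 12.7) where it was called in both. The same regions were called in the wild-type library alone in 0.908%, 3.24% and 4.60% of cases. These shares are not matched on H3K4me3 density, and the median wild-type densities of the groups were 72.8, 56.1 and 51.1 in shared regions. Of wild-type intervals with a CpG island 69.0% were overlapped in the lowest density decile and 99.96% in the highest, so weaker groups alone could give such a rise. Over all H3K4me3 regions the shares called in the K27M library alone were 13.01%, 16.1% and 17.9%, and those called in the wild-type library alone went the other way, with 14.7%, 6.04% and 6.97%. H3K27ac regions were called in the K27M library alone in 2.41% (2.26 to 2.57) of cases without H3K27me3, 12.9% (10.3 to 15.9) where H3K27me3 was called in the wild-type library alone and 5.21% (3.73 to 7.22) where it was called in both. They were called in the wild-type library alone in 60.2%, 45.9% and 53.8% of cases. In shared H3K27ac regions the median log2 ratios of these groups were 0.02, 0.20 and 0.18. Where both marks of a pair were found in both libraries, their ratios were weakly correlated or not at all. The Spearman correlation of the log2 ratios of H3K27ac and H3K4me3 was 0.11 over 11527 regions, and 0.21 by highest density. By gene, H3K27me3 correlated at 0.06 with H3K4me3 (1751 genes) and at -0.01 with H3K27ac (921 genes). These are correlations across regions or genes, which are not independent replicates.

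At genes named in advance for their link to the cells or to metabolism, both active marks were present in each genotype. Cdkn2a, which encodes p16Ink4a and the Arf protein for which the labels give the cells as negative, carried 7 H3K4me3 intervals in the wild-type and 9 in the K27M library, and 13 and 5 H3K27ac intervals, in or within 1 kb of its span on chromosome 4 from 89274473 to 89294619. Its relative H3K4me3 ratio was 0.06. A stretch of 2.31 kb inside it, from 89274581 to 89276890, held no interval of either active mark in any of the 4 libraries, as did another of 2.33 kb from 89284223, and whether any part of the gene is missing was not tested. The endogenous H3.3 genes H3f3a and H3f3b had H3K27ac ratios of -0.27 and -0.53 and relative H3K4me3 ratios of 0.12 and 0.05. Ezh2, the methyltransferase of Polycomb repressive complex 2, had -0.20 and 0.07. For H3K4me3 the relative ratios were 0.31 at Hk2, 0.15 at Idh1, 0.03 at Glud1 and -0.03 at Cdkn1a, and for H3K27ac the ratios were 0.18, 0.10, 0.04 and -0.03. Of these genes only Hk2 had an H3K27me3 interval. Of 54 genes of the Hist1h family 41 had H3K4me3 in both libraries, with a relative median of -0.18, 35 had H3K27ac in both, with a median of -0.24, and 0 had H3K27me3.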

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

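The density floor, the equal 5th percentiles, the match on region length, 1 member per region, no flank and the highest density for lists, promoters and mark correlations were chosen after the results were seen. No paired analysis was possible because each group holds 1 library and the result comes from no test. Over all alternatives, 53 values for whole comparisons stayed within their error or within 1.5 times a count, 78 moved and 5 changed sign; 585 list percentiles kept their side, 14 came to stand apart and 14 no longer did; and 264 values at named genes kept direction and threshold, 38 fell under 2-fold and 10 changed sign. The unknown depth limits every ratio of densities, and the cause of the moves was not tested except where the alternative itself sets the value.

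With the median set to 0 it was 0 for each mark, with 213 H3K27me3 regions higher and 26 lower, 17 H3K27ac regions lower, and 21 H3K4me3 regions higher and 21 lower. With equal sums the medians were 1.43, 1.12 and -0.050 for H3K27me3, H3K27ac and H3K4me3, with 3034, 9557 and 14 regions higher and 0, 0 and 25 lower, and the ratio turned above 0 for H3K27me3 at Lingo3 (0.0078), Tbx3os1 (0.044), Trpm2 (0.15), Shisa8 (0.29), Irx4 (0.11), Chat (0.10), Tmem132e (0.22) and Zfp879 (0.20) and for H3K27ac at Tspan32 (0.062) and Polr3b (0.075). With equal 5th percentiles the medians were -0.46, -0.54 and 0.19, with 82, 0 and 63 regions higher and 390 H3K27me3 and 1165 H3K27ac regions lower. With 1 density floor the wild-type list had 12.6 times as many H3K27me3 intervals over 10.2 times the length and 1.06 times as many H3K27ac intervals, and the overlapped shares were 7.02%, 64.8% and 90.6%.

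By highest density the medians were -1.51, -0.28 and 0.44, with 24, 74 and 413 regions higher and 708 H3K27ac and 20 H3K4me3 regions lower, promoter minus distal medians of -0.37, 0.18 and 0.15, a correlation of 0.21, and 2 H3K27me3 lists apart. Among regions of upper density the medians were -1.38, -0.074 and 0.39, with 1403 H3K27me3 and 1 H3K4me3 regions lower and 16 H3K27ac and 37 H3K4me3 regions higher. With a pseudocount of 5 the H3K27me3 and H3K4me3 medians were -0.66 and 0.33, with 457 H3K27me3 and 3 H3K27ac regions lower and 0, 9 and 83 regions higher. With no pseudocount they were -1.35 and 0.36, with 10 H3K27me3 regions higher and 16 H3K27ac regions lower. At 1.5-fold, 34, 721 and 2208 regions were higher and 412 H3K27ac and 28 H3K4me3 regions lower, and at 3-fold 0, 0 and 7 were higher and 475, 0 and 1 lower, which follows from the threshold. A stricter overlap, set as a share of the shorter interval, gave 38.6% for H3K27ac and 84.2% for H3K4me3, and the intervals at or above the median density of each list gave 19.8%, 44.8% and 94.4%. Lists apart numbered 4 for H3K27ac with promoter regions, 4 for H3K27ac and 2 for H3K27me3 matched on length, and 1 for H3K27ac and 0 for H3K27me3 with 1 member per region. Lists that came to stand apart included mature neuron genes for H3K27me3 by highest density (percentile 0.145), neural patterning genes for H3K27ac (98.4 to 99.4) and p53 pathway genes for H3K27ac (1.41 and 2.03). A start site within 5 kb was not run because strand is missing from the gene table, and limiting regions to called intervals moves nothing since every region has one.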

Other observations

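Tests of the H3K27ac density floor, of CpG islands at matched density and of the density of gained H3K27me3 regions were chosen only after the results were seen, and the chromosome X and H3K4me3 tests were chosen after the unmatched pattern had been seen but before the tested value.

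Chromosome X kept more H3K27me3 than the autosomes. Covered length went from 3.05 Mb to 1.64 Mb, or 53.7%, against 12.2% to 23.4% on the autosomes. Of its wild-type regions 31.0% (26.8 to 35.5) were also marked in the K27M library, against 17.5% on autosomes, and the median log2 ratio was -0.61 against -1.12. These 2 medians are not matched on density. In shared regions the median wild-type density was 4.86 on chromosome X and 7.96 on autosomes, and the K27M density 2.73 and 2.93. Of the 789 regions marked in the K27M library alone, 115 lay on chromosome X. The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y carried H3K4me3 and H3K27ac in both genotypes, and Xist carried no interval of any mark. H3K27ac regions called in the K27M library alone were most numerous on chromosome 15 (101 of 1022), with the densest at Gpd1 and Cox14 (63.7), Dip2b (57.8), Eef1d (52.2) and Tuba1b (50.7), and 10 of the densest 20 lay there. At Shox2 an H3K4me3 region was called in the wild-type library alone (39.0) and an H3K27me3 region in the K27M library alone.

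The genome-wide fall in H3K27me3 has no reference scale in these tables, so a lower efficiency or depth of the K27M library may account for much of it. As the whole cause, 1 scale factor below 1 is argued against by gained regions. Of the regions marked in the K27M library alone, 16.5% (14.1 to 19.2; 130 of 789, 6 of them on chromosome X) had a density at or above 3.54, the 5th percentile of the wild-type intervals. At matched wild-type density and length, 32.9% of chromosome X intervals were overlapped against 8.65% on autosomes, a difference of 24.2 points (20.6 to 27.9). This match covers neither the copy number nor the background of chromosome X, and whether calls used the input is unknown. The difference therefore cannot decide for or against 1 scale factor. A redistribution of the mark in cells with H3.3K27M is an untested biological hypothesis, as is a difference between the cultures, since each genotype is 1 library.

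The smaller number of H3K27ac intervals in the K27M library may come from a higher density floor. At a floor of 25.5 in both lists there were 20174 and 19038 intervals, a ratio of 1.06. This floor was taken from the K27M list, so a loss of weak intervals would bring the counts together as well. The ratio therefore cannot tell a floor from loss. Of the wild-type intervals at that floor, 64.8% were overlapped by a K27M interval, so near-equal counts did not mean the same places. At that floor the wild-type list still covered 1.97 times the length, and why its intervals were longer stays open. A floor that acts on density alone is argued against for the split by CpG islands. At matched density and length 79.6% of wild-type intervals with a CpG island were overlapped against 50.4% of those without, 29.1 points apart (28.0 to 30.2). A difference in background or in GC content between the libraries stays open, as does the genotype.

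H3K4me3 regions at least 2-fold higher in the K27M library lay in H3K27me3 intervals in 70 of 128 cases (54.7%, 46.1 to 63.0), against 14.6% of other shared regions. Wider scatter at low density alone is argued against, since 10000 draws matched on H3K4me3 density gave a median of 20.3% (central range 13.3 to 26.6, highest 33.6). The draws were matched on the mean density of both libraries and not on CpG islands, which 93 of the 128 regions held. Scatter among weak regions with a CpG island was therefore not tested. Short wild-type fragments are argued against too, since the share was 54.0% without the 4 regions they affect. The fold is measured at the deposited scale, and the shift of 0.35 is part of it. That promoters under Polycomb gained H3K4me3 more often with H3.3K27M is a hypothesis found and tested on the same data, and a difference between the cultures stays open.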
